A study of Mus musculus with 7 samples.

How the data were processed

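RNA was taken from FACS-sorted basal cells of mouse mammary glands on day 2 of lactation, and libraries were prepared with the SMARTer v4 protocol, per the labels' protocols. The 7 libraries were assigned to 4 Ctrl and 3 a3a6KO samples by their genotype label. The labels give no batch, litter or pairing, so replicate numbers only name libraries, in the order of their deposition. The sorting markers and gates are not given in the sources used here.

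The deposited file holds 1 signal value per gene and library, gene counts divided by a size factor of each library by the authors with DESeq2, as the deposited file is titled and per the submitters' processing notes. The notes also name STAR 2.4.0, FastQC, Picard and SAMtools with no role stated, and build mm10. The read counter, its settings and its use of strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart by strand. The values are not corrected for gene length. The file has 56440 gene models, of which 31483 were above 0 in any library and 30655 carry no symbol. Symbols that name a gene and a microRNA were taken as the gene, features of more than 1 other gene were left out of lists (298 features), and 14 symbols had been turned into dates.

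Every value above 0 was a whole multiple of one step per library, within 0.01 of a read, so whole reads were recovered for 100% of values. For Ctrl replicate 1 the step is close to 1. Recovered reads per library ran from 9368418 to 21548279. Even numbers made up 61.8% to 63.8% of the recovered counts from 1 to 20, where single reads would give about as many odd as even numbers, and the count models treat each as a read. No molecular identifiers are named in the labels.

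The comparison was made with limma 3.58.1 in R 4.3.3, with an empirical Bayes trend, on log2(value + 1), for the 16889 genes with a value of at least 10 in at least 3 libraries. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are a3a6KO minus Ctrl on the log2(value + 1) scale, which understates changes of low genes. The count tests of edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads were alternatives.

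There were 27 gene lists, covering integrins, basement membrane, the contractile apparatus, signalling, lactation and markers of other cell types. The 26 lists with at least 4 measured members were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The mean of each list per library was compared by exact permutation over the 35 splits of the libraries, where the smallest p is 0.0286. After adjustment over the 27 lists, a single list at this p could not fall under 0.05. The tests, lists and the rule for named genes were chosen before the data were examined. The rule names 4 integrin genes and up to 12 genes of each direction past the threshold. The latter needed a mean value of at least 50 and no overlap of the groups. Where fewer than 6 passed, genes meeting the same mean and overlap conditions were added by smallest p, up to 6. For each list the rule names up to 4 members with the smallest p and, for cell types, up to 3 with the highest level. Predicted genes were excluded. Genes outside the rule are said to have been chosen after their values were seen, or are marked as outside it.

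The alternatives were other pseudocounts, filters, scalings, library weights, no trend, robust empirical Bayes, the count tests, the milk protein mean as a covariate and leaving out each library. Alternatives added after the data were seen were reads thinned to equal depth, exact symbols only and DESeq2 leaving out each library. The scripts were tested on simulated counts drawn for the 16889 genes with 200 changed genes. With no gene changed, limma and edgeR made 0 calls and DESeq2 14. Camera called 0 of 26 lists when genes were independent, which does not cover correlated genes.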

Results

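Gene expression was measured by RNA sequencing in basal cells of the mouse mammary gland, which comprise the contractile myoepithelial cells that surround the milk-producing luminal layer and rest on the basement membrane. The cells were sorted by flow cytometry from fresh tissue on day 2 of lactation. There were 4 control libraries (Ctrl) and 3 libraries from mutants named for the integrin subunits α3 and α6 (a3a6KO), described by the submitters as biological replicates. Subunit α3 pairs with β1, and α6 with β1 or β4, to form receptors for laminin, a main protein of the basement membrane. The sample titles mark controls as Blg negative and mutants as Blg positive. As far as the study is known, Blg stands for a Cre under the beta-lactoglobulin promoter, meant to delete both subunits in luminal cells, and the comparison asks how the neighbouring basal cells differed. The deletion in luminal cells was not analysed here. Blg was present in every mutant and in no control, so the design does not separate it from the loss of the integrins. The deposited values corresponded to 14480615, 17808127, 17041681 and 21548279 reads in Ctrl replicates 1 to 4 and to 18454773, 10861835 and 9368418 reads in a3a6KO replicates 1 to 3.

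The transcripts of the targeted genes were present at similar levels in both groups of basal cells. Itga3 (identifier GSMG0007263, chromosome 11, 95044476 to 95076811, mm10) had normalised read counts of 719, 542, 465 and 654 in Ctrl replicates 1 to 4 and of 494, 581 and 818 in a3a6KO replicates 1 to 3, with means of 595 ± 113 (SD, n = 4) and 631 ± 168 (SD, n = 3). Itga6 (GSMG0021209, chromosome 2, 71786928 to 71858427) had 10338, 10603, 7764 and 8678 in Ctrl and 9083, 8343 and 8574 in a3a6KO. The log2 fold change, a3a6KO minus Ctrl, was 0.07 (SE 0.21, 95% interval −0.41 to 0.56) for Itga3 and −0.10 (SE 0.15, −0.43 to 0.24) for Itga6, with limma adjusted p = 0.955 and 0.918. The sign for Itga3 turned with library weights (−0.06), without a3a6KO replicate 3 (−0.13) and without Ctrl replicate 3 (−0.039), and leaving out 1 library gave −0.18 (Ctrl replicate 3) to −0.034 (Ctrl replicate 2) for Itga6, which had −0.19 under quantile normalization. These values cover whole genes, so a deletion of single exons would not necessarily show in them. Among their β partners, Itgb1 had a log2 fold change of 0.08 (SE 0.16), which turned to −0.05 under quantile normalization, −0.0029 with library weights and −0.06 without a3a6KO replicate 3, and Itgb4 of −0.45 (SE 0.18, adjusted p = 0.741). Ctrl replicate 4 stood above the other controls for Itgb1, at 21379 against 17242 to 17776.

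No single gene differed between the groups at an adjusted p under 0.05 in limma, where 16889 genes were tested. Among upward genes with no overlap of the groups, those with the smallest unadjusted p included Egfl7 and Cdh5 of the endothelial list. Egfl7, an angiogenic factor secreted by endothelial cells, averaged 416 ± 65.9 (SD, n = 4) in Ctrl and 971 ± 156 (SD, n = 3) in a3a6KO, a log2 fold change of 1.22 (SE 0.17, limma adjusted p = 0.497). Cdh5, the cadherin of endothelial junctions, averaged 384 and 762, with a log2 fold change of 1.01 (SE 0.17). The others of the 6 named for the smallest unadjusted p were Grap (1.22, SE 0.18), septin 4, listed in the file under a date (0.97, SE 0.14), Ushbp1 (0.98, SE 0.16) and Kank3 (0.93, SE 0.16). For Grap, Ctrl replicate 4 stood apart at 256, against 165 to 180 in the other controls. In the downward direction the 6 genes named by the same rule were Apod, which encodes a lipid-binding lipocalin, with 538 ± 71.6 (SD, n = 4) in Ctrl and 279 ± 49.99 (SD, n = 3) in a3a6KO and a log2 fold change of −0.95 (SE 0.17), Calml3 (−1.45, SE 0.27), Psd2 (−1.21, SE 0.22), Enkur (−1.81, SE 0.35), Cited4 (−1.15, SE 0.23) and Bglap3 (−1.50, SE 0.34). The 12 genes were picked among those with no overlap of the groups, so their lack of overlap is not a result. None of the 12 passed in limma.

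**Figure D1:**
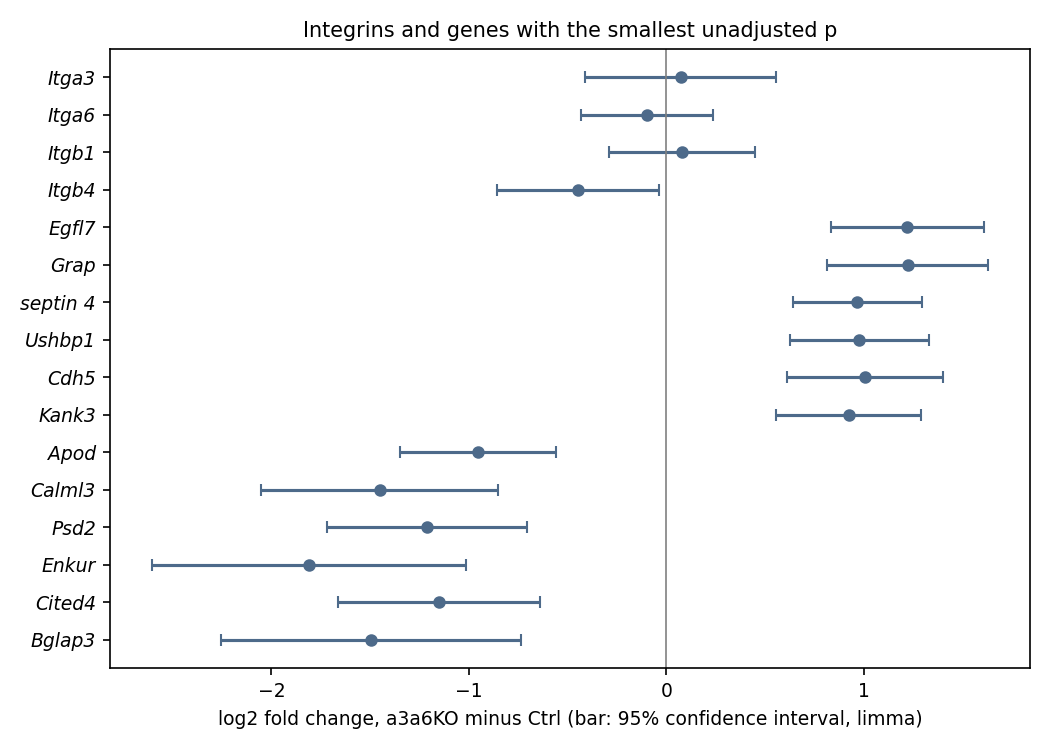
Log2 fold change, a3a6KO (n = 3) minus Ctrl (n = 4), on the horizontal axis, for 4 integrin genes and for 6 genes of each direction. The 6 had the smallest unadjusted p among genes with a mean value of at least 50 and no overlap of the groups. Points are limma estimates and bars 95% confidence intervals. The intervals of Itga3 (−0.41 to 0.56) and Itga6 (−0.43 to 0.24) include 0, and none of the 16 genes passed after adjustment.

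At an unadjusted p under 0.05 limma held 1068 genes, 599 higher and 469 lower in a3a6KO, where 844 were expected by chance. The groups did not overlap in 1269 genes, 7.51% of those tested against 5.71% expected by chance. The edgeR quasi-likelihood test on recovered reads also called 0 of 17228 genes, with 1031 at an unadjusted p under 0.05, whereas DESeq2 called 73, of which 55 were higher and 18 lower. Of the 55, 9 belonged to the endothelial list, where 0.075 would be expected by chance if genes were independent. The members of this list were not, with an estimated correlation of 0.599, so the expected number says little of how often several would be called together. Leaving out 1 library gave 5 endothelial calls (without Ctrl replicate 2 or a3a6KO replicate 3) to 12 (without Ctrl replicate 4), with 6 without a3a6KO replicate 2. The DESeq2 count was 32, 27, 47 and 134 without Ctrl replicates 1 to 4 in turn and 83, 61 and 49 without a3a6KO replicates 1 to 3. Of the 73 genes, 30, 24, 34 and 60 were called again without a control and 37, 32 and 25 without a mutant library. The higher calls numbered 26, 19, 34 and 113 without the controls in turn and 51, 38 and 27 without the mutant libraries, and the lower calls 6, 8, 13 and 21, and 32, 23 and 22. In data simulated from these libraries with known changes, DESeq2 made 31 calls among unchanged genes in 132, and limma 2 in 72. Of genes changed 4-fold, 2-fold and 1.5-fold, limma recovered 90.6%, 21.8% and 0%, and DESeq2 96.9%, 61.8% and 6.17%.

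Transcripts of endothelial cells, which line blood vessels, were higher in a3a6KO. Of the 18 endothelial markers measured, 17 had a fold change above 1, 11 had no overlap of the groups, and the list's median log2 fold change was 1.02. Cldn5, a tight junction protein of vessels, averaged 579 ± 258 (SD, n = 4) in Ctrl and 1575 ± 391 (SD, n = 3) in a3a6KO, a log2 fold change of 1.52 (SE 0.33). Pecam1, an adhesion molecule of endothelial cells, averaged 888 ± 244 and 1771 ± 229 (1.03, SE 0.22), Eng 1058 ± 208 and 2096 ± 416 (0.99, SE 0.20), and Tie1, a vascular receptor tyrosine kinase, 452 ± 116 and 978 ± 134 (1.14, SE 0.20). The exception was Ecscr, at −0.24, named after its value was seen. None of the 18 passed over all genes in limma, and 16 passed when adjusted over the list alone. The list passed camera with a preset correlation (adjusted p = 6.0e-18), and did not with an estimated correlation (adjusted p = 0.432). The list mean was 8.47 ± 0.32 (SD, n = 4) in Ctrl and 9.43 ± 0.28 (SD, n = 3) in a3a6KO on the log2 scale, and each a3a6KO library lay above each control. The exact permutation test of the list means gave p = 0.0571, two-sided, and an adjusted p of 0.551. With Ctrl replicates 1 to 3 set against the other 4 libraries the median was −1.02 (camera adjusted p = 1.8e-16).

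**Figure D2:**
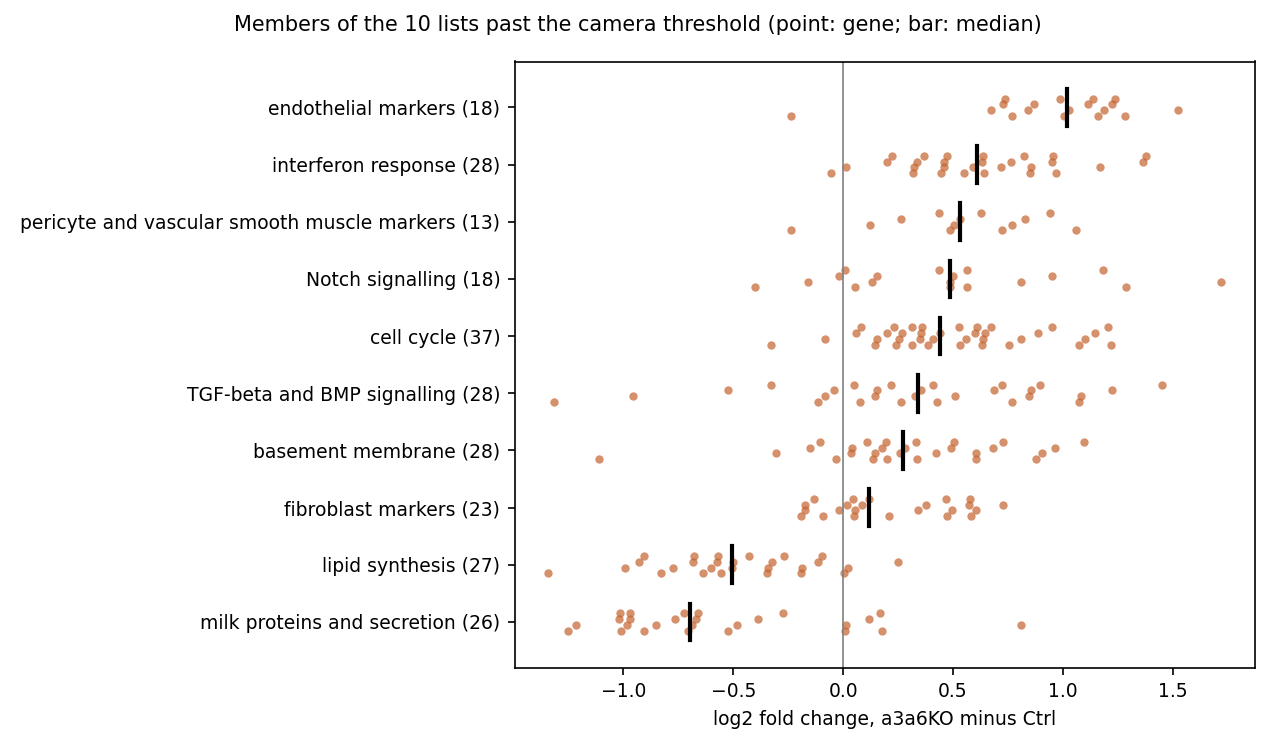
Log2 fold change, a3a6KO minus Ctrl, on the horizontal axis, of the measured members of each of the 10 lists that passed camera with a preset correlation; points are genes, black bars list medians, and numbers in brackets the members measured. The medians ran from −0.70 for milk proteins to 1.02 for endothelial markers, and 17 of the 18 endothelial markers lay above 0.

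In all, 10 of 26 tested lists passed camera with a preset correlation, 8 higher and 2 lower in a3a6KO. None of the 10 passed with an estimated correlation, and by exact permutation of list means the smallest adjusted p was 0.551. Fry called 0 lists moving one way, and 2 in its mixed test, Notch signalling (adjusted p = 0.0357) and endothelial markers (adjusted p = 0.0478). The number of lists called was 8 without a3a6KO replicate 3 and 15 without a3a6KO replicate 2.

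Genes of Notch signalling, through which neighbouring cells set each other's fate, were higher in a3a6KO, with 15 of 18 members above 1 and a median log2 fold change of 0.49. Dll4, a Notch ligand of vessels, averaged 202 ± 85.2 (SD, n = 4) and 651 ± 229 (SD, n = 3), a log2 fold change of 1.72 (SE 0.34). The receptor Notch4 (1.18, SE 0.32) and the Notch target Nrarp (0.95, SE 0.19) also passed when adjusted over the list alone. Over all genes none passed in limma, and DESeq2 called Dll4 and Nrarp. The list's camera adjusted p was 4.8e-05, and with an estimated correlation the adjusted p was 0.432. The exact permutation p of the Notch signalling mean was 0.0286, the smallest that 35 splits can give, and its adjusted p 0.551. An adjusted p under 0.05 was out of reach for a single list. The median was 0.27 without a3a6KO replicate 3 and 0.27 with library weights. Dll4 and Notch4 are also transcripts of endothelial cells, whose markers were higher in the same libraries.

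The markers of pericytes and vascular smooth muscle, the cells that wrap vessels, had 12 of 13 members above 1 and a median log2 fold change of 0.53 (camera adjusted p = 9.9e-05, and adjusted p = 0.511 with an estimated correlation). Gja4, a gap junction gene of vessels, averaged 116 ± 7.02 (SD, n = 4) in Ctrl and 210 ± 47.6 (SD, n = 3) in a3a6KO (0.83, SE 0.20), the 1 member that passed adjusted over the list alone, and Rgs5 1491 ± 610 and 2018 ± 136 (0.53, SE 0.29; 0.33 without Ctrl replicate 1). For this list the mean of Ctrl replicate 4 stood apart, at 7.50 against 6.88 to 6.92 in the other controls. It lay above that of a3a6KO replicate 1, at 7.37, so the groups overlapped. Fibroblast markers had 17 of 23 members above 1 and a median of 0.12 (camera adjusted p = 0.0458, and adjusted p = 0.645 with an estimated correlation). The fibroblast call ended in 9 of 20 alternatives, with an adjusted p of up to 0.251, among them leaving out Ctrl replicate 1 (median 0.17), Ctrl replicate 2 (0.11), Ctrl replicate 4 (0.18), a3a6KO replicate 2 (0.26) or a3a6KO replicate 3 (0.15). The fibroblast median was 0.37 without a3a6KO replicate 1 and 0.22 without Ctrl replicate 3. The highest fibroblast list mean was that of a control, Ctrl replicate 3 at 9.45, against 8.92, 9.23 and 9.27 in a3a6KO. Of the red blood cell genes 3 were measured, too few to test as a list, and all 3 had a fold change above 1. The list mean of Ctrl replicate 1 was the lowest, at 2.42 against 5.94, 5.98 and 6.85 in the other controls and 7.49, 7.68 and 6.32 in a3a6KO. Hba-a1, a haemoglobin alpha chain, averaged 88.4 ± 59.6 (SD, n = 4) and 383 ± 45.0 (SD, n = 3), and Hbb-bs, a beta chain, 71.0 ± 52.1 and 220 ± 32.6. Both passed adjusted over the list alone, with log2 fold changes of 2.50 (SE 0.65) and 2.13 (SE 0.78), which were 1.84 and 1.31 without Ctrl replicate 1. DESeq2 called Hba-a1 over all genes and limma neither. For Hba-a2 the groups overlapped (0.96, SE 1.51), and its sign turned without Ctrl replicate 1 (−0.43). Haemoglobin genes are near-identical copies, so reads can be split between them.

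Basement membrane genes were higher in a3a6KO in 23 of 28 members, with a median log2 fold change of 0.27. The collagen-binding protein Sparc averaged 88527 ± 2707 (SD, n = 4) and 125790 ± 6589 (SD, n = 3), a log2 fold change of 0.51 (SE 0.18). The nidogens, which link laminin to collagen IV, followed in the same direction, with Nid1 at 0.68 (SE 0.18) and Nid2 at 0.97 (SE 0.29). The laminin chain Lamc3 had 1.10 (SE 0.32) at a low level, averaging 24.6 in Ctrl and 52.4 in a3a6KO. For Nid2, Ctrl replicate 4 stood apart at 679, against 286 to 350 in the other controls. In limma no member passed over all genes, and 0 when adjusted over the list alone, while DESeq2 called Sparc. The camera adjusted p was 3.9e-05, and with an estimated correlation the adjusted p was 0.592. The basement membrane median was 0.17 without a3a6KO replicate 3 and with library weights. Several of these genes are also made by vessels. TGF-beta and BMP signalling had 21 of 28 members above 1 and a median of 0.34 (camera adjusted p = 9.0e-04, and adjusted p = 0.565 with an estimated correlation). Tgfb1, which encodes the growth factor TGF-β1, averaged 144 ± 26.3 and 268 ± 43.9 (0.90, SE 0.20) and was the 1 member that passed adjusted over the list alone, and the 1 that DESeq2 called over all genes. The BMP target Id1 had 0.86 (SE 0.29) and the activin inhibitor Fst 1.22 (SE 0.43). The TGF-beta and BMP signalling call ended without a3a6KO replicate 3 (median 0.25, adjusted p = 0.107), and the median was 0.22 without Ctrl replicate 1. For this list too the groups overlapped, with a mean of 8.31 in a3a6KO replicate 2 and of 8.48 in Ctrl replicate 4.

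Genes induced by interferons were higher in a3a6KO in 27 of 28 members, with a median log2 fold change of 0.61. Irf7, a transcription factor of this response, averaged 842 ± 347 (SD, n = 4) and 1473 ± 423 (SD, n = 3), a log2 fold change of 0.86 (SE 0.31), Ifi44 had 1.36 (SE 0.47) and the peptide transporter Tap1 0.47 (SE 0.18). Neither limma nor DESeq2 called a member over all genes, and in limma 0 passed when adjusted over the list alone. The camera adjusted p was 3.3e-07, and with an estimated correlation the adjusted p was 0.592. The groups overlapped, with a list mean of 9.12 in Ctrl replicate 2 and of 8.83 and 8.82 in a3a6KO replicates 2 and 3. The interferon response median was 0.33 without a3a6KO replicate 1 and 0.39 without Ctrl replicate 1. Immune cell markers had a median of 0.08 and 10 of 19 members above 1 (camera adjusted p = 0.980), and leaving out 1 library moved the median from −0.38 (without Ctrl replicate 1) to 0.49 (without Ctrl replicate 3). It was −0.21 without Ctrl replicate 2 and −0.31 without a3a6KO replicate 3. The list passed with the milk protein mean as a covariate (0.48, adjusted p = 0.0191), the 1 of its 20 alternatives that did.

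Cell cycle genes had 35 of 37 members above 1, with a median log2 fold change of 0.44. Cdc20, an activator of the anaphase-promoting complex, averaged 138 ± 51.9 (SD, n = 4) and 243 ± 32.1 (SD, n = 3), a log2 fold change of 0.89 (SE 0.29), Mcm3, a subunit of the replicative helicase, had 0.36 (SE 0.14) and the cyclin Ccnb2 1.08 (SE 0.52; 0.67 without Ctrl replicate 2). The camera adjusted p was 3.5e-06, and with an estimated correlation the adjusted p was 0.645. The list mean averaged 6.15 ± 0.71 (SD, n = 4) in Ctrl and 6.66 ± 0.18 (SD, n = 3) in a3a6KO, a difference below the SD of the controls. The means were 5.51 and 5.56 in Ctrl replicates 1 and 2, 6.78 and 6.75 in Ctrl replicates 3 and 4, and 6.55, 6.55 and 6.86 in a3a6KO. Ctrl replicates 3 and 4 were also the higher controls for luminal markers (7.83, 7.67, 8.73 and 9.10 in Ctrl replicates 1 to 4) and immune cell markers (4.95, 5.36, 6.66 and 6.50). In a3a6KO replicates 1 to 3 these means were 8.07, 8.20 and 8.83, and 5.64, 5.34 and 6.70. The cell cycle median was 0.28 without Ctrl replicate 1, 0.69 without Ctrl replicate 3 and 0.67 without Ctrl replicate 4, and 0.83 with the milk protein mean as a covariate.

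Genes of lipid synthesis were lower in a3a6KO in 24 of 27 members, with a median log2 fold change of −0.51. Fads1, a fatty acid desaturase, averaged 9381 ± 693 (SD, n = 4) and 6315 ± 849 (SD, n = 3), a log2 fold change of −0.58 (SE 0.14), and Gpam, which catalyses the first step of glycerolipid synthesis, 352 ± 17.96 and 240 ± 11.8 (−0.55, SE 0.13). These were the 2 members that passed adjusted over the list alone, and over all genes DESeq2 called Fads1 and limma none. Acaca, which makes malonyl-CoA, had −0.68 (SE 0.22) and Dgat2, which completes triglyceride synthesis, −1.34 (SE 0.43; −0.84 without a3a6KO replicate 2). The camera adjusted p was 4.4e-06, and with an estimated correlation the adjusted p was 0.565. The lipid synthesis median was −0.33 without a3a6KO replicate 1 and −0.30 with the milk protein mean as a covariate. The groups overlapped, with a list mean of 10.37 in a3a6KO replicate 3 and of 10.13 and 10.28 in Ctrl replicates 1 and 2. The exact permutation p of the lipid synthesis means was 0.171. Genes of milk proteins and secretion were lower in 20 of 26 members, with a median of −0.70 (camera adjusted p = 0.0173, and adjusted p = 0.946 with an estimated correlation). Of the 4 members with the smallest p, Cd36 was higher in a3a6KO and the others lower. Cd36 averaged 5218 ± 2134 (SD, n = 4) in Ctrl and 8824 ± 2487 (SD, n = 3) in a3a6KO (0.81, SE 0.32). Csn2, which encodes beta-casein, averaged 224684 ± 181976 (SD, n = 4) in Ctrl and 98189 ± 70030 (SD, n = 3) in a3a6KO (−0.97, SE 0.75; −1.52 without a3a6KO replicate 3 to −0.50 without Ctrl replicate 4), and Csn1s2b 9238 ± 4918 and 3858 ± 1907 (−1.22, SE 0.46). The list took 2.37%, 1.87%, 7.60% and 9.53% of the values in Ctrl replicates 1 to 4 and 1.47%, 2.32% and 4.39% in a3a6KO replicates 1 to 3. The call for milk proteins and secretion ended without Ctrl replicate 3 (median −0.37), Ctrl replicate 4 (−0.21), a3a6KO replicate 1 (−0.30) or a3a6KO replicate 2 (−0.54). The milk protein median was −1.07 without Ctrl replicate 1, −1.22 without Ctrl replicate 2 and −1.23 without a3a6KO replicate 3.

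**Figure D3:**
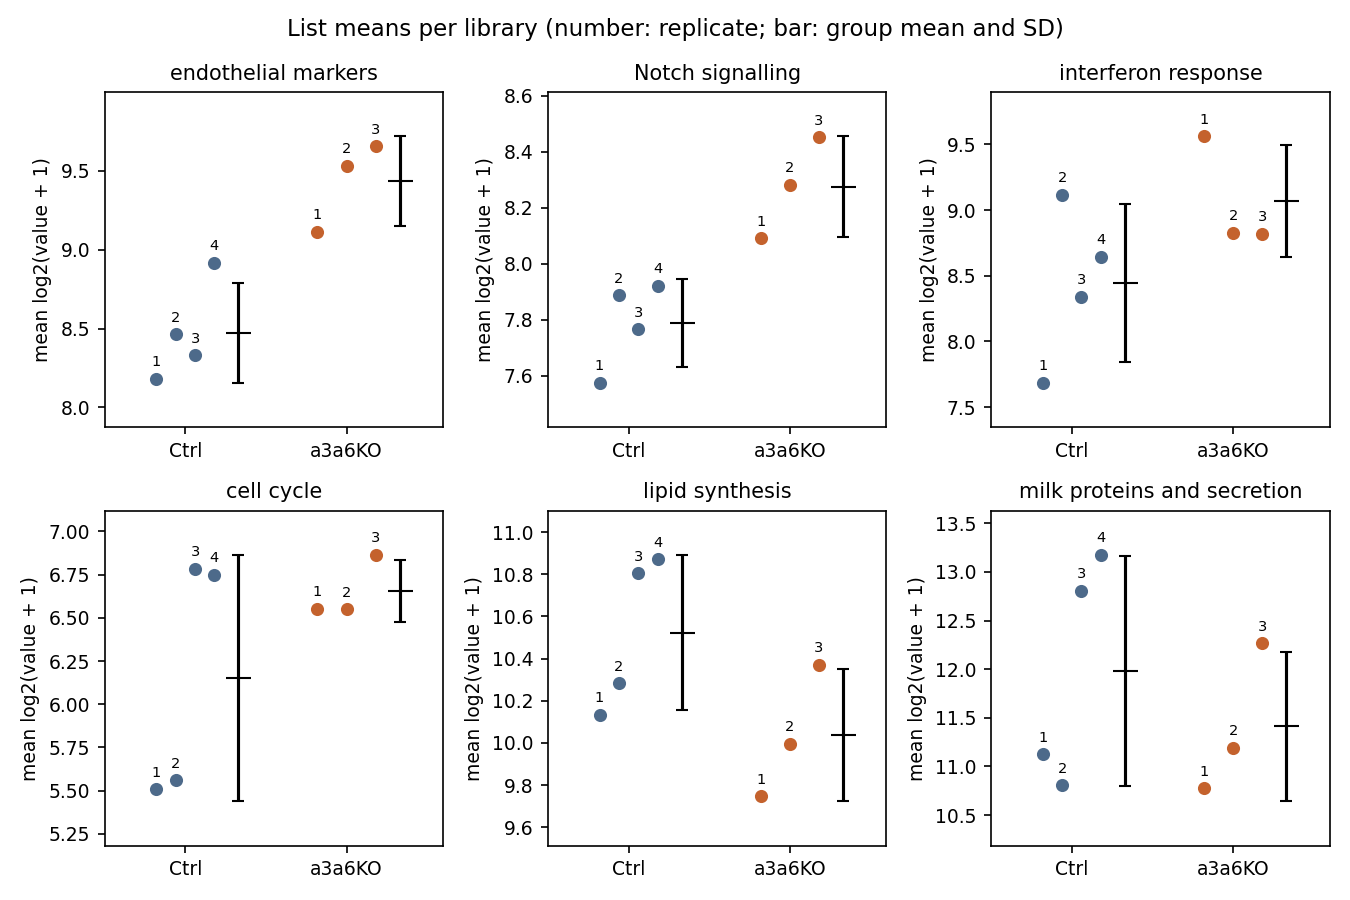
Mean log2(value + 1) of the measured members of 6 lists on the vertical axes, in the 4 Ctrl and 3 a3a6KO libraries; each point is a library with its replicate number, and bars give the group mean and SD. The groups did not overlap for endothelial markers and Notch signalling and overlapped for the other lists shown; in the cell cycle panel Ctrl replicates 1 and 2 lay at 5.51 and 5.56.

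The genes that define basal and myoepithelial cells did not pass in either direction. Basal cell identity genes had 11 of 24 members above 1, a median log2 fold change of −0.04 and a camera adjusted p of 0.944. Krt14 (0.35, SE 0.24; 0.10 without a3a6KO replicate 3 and 0.54 without a3a6KO replicate 2), Krt5 (−0.03, SE 0.16; 0.09 without a3a6KO replicate 1) and Acta2, smooth muscle actin (0.15, SE 0.31; 0.064 without Ctrl replicate 2 to 0.28 without Ctrl replicate 4), were looked up after the values were seen. The myoepithelial contractile apparatus had 8 of 22 members above 1 and a median of −0.10 (camera adjusted p = 0.0927), and passed without Ctrl replicate 3 (−0.14), without a3a6KO replicate 2 (−0.13) and with both count tools (−0.11 each). The contractile median was −0.025 without Ctrl replicate 1 (adjusted p = 0.601) and −0.052 without a3a6KO replicate 3 (adjusted p = 0.412). Its members with the smallest p included Nexn, an actin-binding protein, at 1676 ± 201 (SD, n = 4) in Ctrl and 1182 ± 92.5 (SD, n = 3) in a3a6KO, and Oxtr, the oxytocin receptor through which milk ejection is triggered, at 116511 ± 17135 and 80558 ± 26523 (−0.57, SE 0.26). Integrins and laminin receptors had 8 of 17 members above 1 and a camera adjusted p of 0.993, with a median of −0.10, a mean of 0.0015 and an upward test direction. Bcam, a receptor for the laminin α5 chain, was the 1 member that passed adjusted over the list alone, at 4144 ± 761 and 7812 ± 1055 (0.93, SE 0.18), and over all genes DESeq2 called it and limma did not.

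The remaining lists did not pass with the preset correlation. The median log2 fold change was 0.0015 for focal adhesion and actin cytoskeleton (camera adjusted p = 0.814; its sign turned under TMM factors, equal totals and quantile normalization), 0.20 for SRF, MRTF and YAP targets (0.0995), 0.04 for prolactin and STAT5 signalling (0.980), 0.14 for involution and STAT3 (0.315) and 0.11 for p53 targets (0.0927). It was 0.05 for apoptosis (0.224), −0.01 for Wnt signalling (0.944), 0.17 for the unfolded protein response (0.117), 0.08 for immediate-early and dissociation stress genes (0.776) and 0.35 for Schwann cell and nerve markers (0.0729). Luminal markers had a median of −0.16, a mean of 0.03 and a downward test (0.980), and adipocyte markers a median of −0.66, a mean of −0.36 and an upward test (0.948). Without a3a6KO replicate 2, SRF, MRTF and YAP targets (median 0.19), involution (0.23), p53 targets (0.20), apoptosis (0.10), the unfolded protein response (0.25) and immediate-early genes (0.40) passed. SRF, MRTF and YAP targets (0.25) and the unfolded protein response (0.30) also passed without Ctrl replicate 4, and p53 targets without Ctrl replicate 3 (0.17). With edgeR p53 targets (0.097) passed, and with DESeq2 p53 targets (0.094) and SRF, MRTF and YAP targets (0.18). Involution (0.29) and the unfolded protein response (0.27) passed with the milk protein mean as a covariate. Schwann cell markers passed without Ctrl replicate 1 (0.53) or a3a6KO replicate 1 (0.67), and had 0.22 without Ctrl replicate 2 and without a3a6KO replicate 3. Other libraries left out moved the medians towards 0. Without Ctrl replicate 1 the median was 0.018 for the unfolded protein response, 0.12 for SRF, MRTF and YAP targets, 0.029 for apoptosis and 0.054 for involution. Without a3a6KO replicate 3 it was 0.029 for the unfolded protein response, 0.00049 for apoptosis and cell death, −0.0064 for p53 targets and −0.091 for involution, and without Ctrl replicate 3 it was 0.019 for apoptosis. For prolactin and STAT5 signalling the mean was −0.03 and the test upward, and for Wnt signalling the mean was 0.01 and the test downward. Gdf15, a stress-induced cytokine listed as a p53 target, had 1.39 (SE 0.33) and was called by DESeq2. The 4 Wnt members with the smallest p were Nkd2 (1.65, SE 0.46), Dkk3 (−0.54, SE 0.16), Lgr4 (−0.52, SE 0.16) and Sfrp1 (−0.49, SE 0.17). Those of the luminal list were Muc15 (−1.39, SE 0.41), Aldh1a3 (1.29, SE 0.40), Ly6a (0.76, SE 0.26) and Kit (1.30, SE 0.59; 0.81 without Ctrl replicate 2). Nkd2, Aldh1a3 and Kit had low levels, averaging 16.5, 10.1 and 24.4 in Ctrl and 48.5, 25.6 and 51.7 in a3a6KO. None of the genes named in this paragraph passed in limma.

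The libraries did not separate by group along the first principal component, which held 33.0% of the variance (exact permutation p = 0.486), nor along the second with 19.9% (p = 0.343, exact permutation). Along the third, with 16.2%, the means were −16.5 in Ctrl and 21.9 in a3a6KO (exact permutation p = 0.114). There a3a6KO replicates 1 and 2 lay at 39.4 and 41.4, above every control, and a3a6KO replicate 3 at −15.0, within the range of the controls. Pearson correlations between libraries, across genes, averaged 0.956 within Ctrl, 0.948 within a3a6KO and 0.952 between the groups. The share of mitochondrial transcripts averaged 1.29% ± 0.36 (SD, n = 4) and 1.53% ± 0.51 (SD, n = 3), and that of ribosomal protein genes 0.558% and 0.551%. Between 15956 and 16810 genes had a value of at least 10, with Ctrl replicate 3 at 15956 below the other controls, at 16452 to 16472. Reads per library did not pass an exact permutation test between the groups (p = 0.2).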

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

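The genes and list means looked at here include some chosen after their values were seen; no test was chosen after the result. In 6 results 1 of the 4 control libraries stood far from the others, by a gap that took up most of the range of the controls, and of 121 results looked at about 6.05 would be so by chance. Ctrl replicate 4 was the high library for Itgb1 (gap over range 0.871, 21379 against 17242 to 17776), Grap (0.840, 256 against 165 to 180) and Nid2 (0.837, 679 against 286 to 350). It was also high for the mean of pericyte and vascular smooth muscle markers (0.925, 7.50 against 6.88 to 6.92). Ctrl replicate 1 was high for Tes, a focal adhesion gene (0.832, 22563 against 17853 to 18647). Ctrl replicate 3 had the fewest genes at a value of at least 10 (0.961, 15956 against 16452 to 16472).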

How the results depend on the processing

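The thinned reads, exact symbols, DESeq2 leaving out a library and the use of the median for a list's direction were chosen after seeing the data. Limma called 0 genes under every alternative run with it, and edgeR, run only with all libraries, also called 0. With all libraries they held 1068 and 1031 genes at an unadjusted p under 0.05. DESeq2 called 73, 55 higher and 18 lower, and the cause of the difference was not tested. Lists past the threshold numbered 10, from 8 to 15 on leaving out 1 library, and 0 with an estimated correlation or with fry's one-direction test, while fry's mixed test called 2. With the estimated correlation the endothelial markers (median 1.02) had adjusted p = 0.432, because a correlation of 0.599 replaced 0.01 for this list. Fry's one-direction test gave them an adjusted p of 0.104. In the alternatives tested with the preset correlation they passed, with medians of 0.87 to 1.16. The lists' direction was first taken from the test and then from the median, which is the value printed. By the median 31 of 520 list values turned sign and by the test 46, with 0 of lists that passed under either. Of 1932 values of 88 named genes, 20 turned sign, in 8 genes, and 32 passed, with DESeq2. Of the scalings, equal totals moved the median of all genes farthest from 0, to −0.022.

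The log2 fold changes that turned sign belonged to results that had not passed, and the cause was not tested. The focal adhesion and actin cytoskeleton median was −0.00080 with a filter at 50, −0.0024 with TMM factors, −0.017 at equal totals, −0.042 under quantile normalization, −0.0042 with edgeR and −0.0072 with DESeq2. Quantile normalization gave −0.051 for Itgb1, −0.038 for Trp63 (outside the rule for named genes) and −0.015 for Krt19. Library weights gave −0.057 for Itga3 and −0.0029 for Itgb1. Trp63 was −0.0037 at equal totals and −0.00013 with thinned reads, which gave 0.015 for Wnt signalling. Immune cell markers had −0.074 with edgeR and −0.071 with DESeq2. With the milk protein mean as a covariate, luminal markers had 0.22, adipocyte markers 0.033 and Trf 0.041. Leaving out 1 library gave −0.18 (Ctrl 3) to 0.018 (a3a6KO 1) for integrins and laminin receptors, −0.065 (Ctrl 2) to 0.0057 (a3a6KO 1) for basal cell identity and −0.43 (a3a6KO 3) to 0.16 (Ctrl 4) for luminal markers. It gave −0.15 (a3a6KO 3) to 0.20 (a3a6KO 2) for prolactin and STAT5 signalling, −0.091 to 0.23 for involution and STAT3 and −0.0064 to 0.20 for p53 targets, with the same libraries left out. Ranges were −0.090 (a3a6KO 1) to 0.018 (Ctrl 1) for Wnt signalling, −0.11 (Ctrl 1) to 0.40 (a3a6KO 2) for immediate-early and dissociation stress, −0.38 (Ctrl 1) to 0.49 (Ctrl 3) for immune cell markers and −0.97 (Ctrl 2) to 0.46 (a3a6KO 2) for adipocyte markers. Of genes, they were −0.13 (a3a6KO 3) to 0.23 (a3a6KO 1) for Itga3, −0.055 to 0.16 for Itgb1 and −0.093 to 0.088 for Krt5 with the same libraries left out. They were −0.11 (a3a6KO 1) to 0.13 (a3a6KO 2) for Trp63, −0.12 (Ctrl 2) to 0.31 (Ctrl 1) for Krt19, −0.12 (Ctrl 1) to 0.30 (a3a6KO 2) for Lcn2 and −0.43 (Ctrl 1) to 2.20 (a3a6KO 3) for Hba-a2. In simulated data of this size, limma recovered 21.8% of genes changed 2-fold and DESeq2 61.8%, so smaller changes of single genes were mostly not detectable here.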

Other observations

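The genes in the next paragraph, the tests on endothelial markers and the tests on milk proteins were chosen after the result was seen.

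Genes outside the fixed lists also stood among the 55 that DESeq2 called higher in a3a6KO, and none of those named here passed in limma. Flt4, a receptor of lymphatic and blood vessel endothelium, averaged 57.2 ± 27.9 (SD, n = 4) in Ctrl and 190 ± 24.8 (SD, n = 3) in a3a6KO (log2 fold change 1.82, SE 0.34), and Gpihbp1, which anchors lipoprotein lipase on capillaries, 1205 ± 420 and 2634 ± 206 (1.19, SE 0.26). Icam2, an endothelial adhesion molecule, had a log2 fold change of 1.08 (SE 0.22). The interferon-induced GTPases Tgtp2 (353 ± 111 and 1089 ± 405, 1.61, SE 0.34) and Iigp1 (1.48, SE 0.41) were called higher too. So were the secreted proteins Fmod, a collagen-binding proteoglycan (8447 ± 440 and 13430 ± 1256, 0.67, SE 0.13), and Fstl1 (0.50, SE 0.11).

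Other splits of the 7 libraries into 4 and 3 were counted. Limma called 0 genes in the real split, a count that any of the 35 splits reaches, so this comparison decides nothing; the highest other count was 90. At an unadjusted p under 0.05, 11 of the 35 gave at least the real 1068, with a highest other count of 2546. At least 10 lists passed in 13 of the 35 splits, with 17 the highest other count, and at least 73 DESeq2 genes in 8 of the 35, with 505 the highest. Chance cannot be excluded for the unadjusted, list and DESeq2 counts. The split of Ctrl replicates 3 and 4 with a3a6KO replicate 3 from the rest called 90 genes in limma and 473 in DESeq2, and that of Ctrl replicates 1 and 2 with a3a6KO replicate 2 gave 505 in DESeq2. These splits point to a structure among the libraries that does not follow the groups.

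For the higher endothelial markers in a3a6KO, the median log2 fold change was 1.03 with reads thinned to equal depth. Unthinned it was 1.02 (SE 0.11 over members). Random thinning keeps the expected ratios of genes with many reads, so this value could hardly have differed and does not decide on lower read depth. A lower share of basal RNA would raise all other cell types alike, and the values do not settle it. The endothelial median exceeded that of immune markers by 0.94 and that of luminal markers by 1.17. Their SEs of 0.17 and 0.21 treat members as independent, while the estimated correlation was 0.599 for endothelial and 0.652 for immune markers. Among other cell types, the median was 0.53 for pericyte, 0.35 for Schwann cell, 0.12 for fibroblast and −0.66 for adipocyte markers. For the 3 red blood cell genes it was 2.13. The immune median itself moved between −0.38 and 0.49 on leaving out 1 library (Ctrl replicate 1 or 3). RNA of endothelial cells in the sort, in different amounts, stays open, since pairs of markers correlated over the 7 libraries, within groups, with a median r of 0.717, against 0.143 at the 95th percentile of 1000 random lists. The most abundant markers, Eng and Pecam1, averaged 2096 and 1771 in a3a6KO, against 609207 for Acta2, and a gate that removes endothelial cells is not given in the sources used here. Whether more vessels in the mutant gland, or a vessel-like change in the basal cells, may lie behind it was not tested, and chance is not excluded.

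Milk protein transcripts were uneven between libraries, and 1 source of milk RNA in different amounts is a candidate explanation: the median SD over libraries was 0.484 for the log2 ratio of a member to the others and 1.19 for the levels. The mean of 24 luminal markers outside the milk list followed the milk list mean over the 7 libraries (Pearson r = 0.936, exact permutation p = 0.00456, adjusted p = 0.00913 over both coefficients; Spearman rho = 0.857, exact permutation p = 0.0238). Without the 2 libraries farthest from the median r was 0.902. Luminal cells or their RNA in the sort may vary between libraries, but the pattern was not particular to luminal markers. Like the milk list, immune cell markers had their highest means in Ctrl replicates 3 and 4 and a3a6KO replicate 3. These were 6.66, 6.50 and 6.70, against 4.95 to 5.64 in the remaining libraries. The adipocyte, involution, unfolded protein response and prolactin list means were highest in the same libraries. So were those of lipid synthesis, at 10.80, 10.87 and 10.37 against 9.75 to 10.28, and of cell cycle, at 6.78, 6.75 and 6.86 against 5.51 to 6.55. Both of these lists passed camera with a preset correlation. A difference in milk synthesis between the animals was not tested.

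Genes of the Notch signalling list correlated within groups with the endothelial mean, with a median r of 0.381, against 0.26 at the 95th percentile of random lists, so RNA of endothelial cells may account for part of the pattern. Without the 2 members that DESeq2 called, Dll4 and Nrarp, the median log2 fold change was 0.46 (SE 0.14), where under 0.24 was set in advance as showing that the call rests on them, and this bound lies within 2 SE. Of the members, Notch3 and Heyl also stand in the pericyte list and Jag2 in the basal list. A change of Notch signalling in the basal cells was not tested apart from this and stays open.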
